A study of Homo sapiens with 6 samples.

How the data were processed

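Gene expression was measured on 6 one-colour Affymetrix arrays with 54675 probe sets. RNA of 3 independent replicates was pooled in equal amounts for each array, per the labels and the series' design. The deposited values are linear intensities, 1 signal per probe set and array, made with MAS5, per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. The deposited intensities had a 2% trimmed mean of about 500 on every array, so they were scaled to a common target before deposit. No detection calls were used here. The data give 1 control array per line. The protocol in the labels and the series' design name a control hairpin vector, while the sample labels call these arrays normal cells, and this difference is not settled. Both hairpins carry the same number in the labels, and they are named here by their identifiers 381 and 1012.

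Probe sets were named with the platform annotation. Of the 54675 probe sets 41097 had 1 gene symbol, 1801 had several and 11777 had none, and 62 were array controls. Symbols were looked up by Entrez identifier in the RefSeq table for 41043 probe sets, and 0 changed. No genome coordinates are given because the annotation used names no build.

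From these intensities log2(signal + 16.9) was computed, the pseudocount being the 25th percentile of all deposited values. A fold value is on this scale, which understates the change of dim genes. Array controls were left out, and probe sets were kept whose mean log2 value exceeded the median over all probe sets, equal to a signal of 54.4. Of 27306 kept probe sets 22310 had 1 symbol, and each gene was represented by its kept probe set with the highest mean over all 6 arrays, giving 11785 genes. No further normalization between arrays was applied. A probe set that is dim in 1 line can pass through its level in the other.

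Genes were tested with limma 3.58.1 in R 4.3.3. All 6 arrays were fitted as 4 groups (control and silenced in each line) with empirical Bayes moderation and an intensity trend. The fit had 2 residual degrees of freedom and a median of 5.92 prior degrees of freedom. Because no control group was replicated, the spread came from the 2 silenced groups, and control arrays were assumed to vary like silenced ones. Contrasts were silenced against control in each line, their average, their difference (the interaction) and the controls of the lines. The hairpins were compared in a fit with the cell line as a block and the arms control, 381 and 1012, with 2 residual and 7.22 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. Since each array is a pool, p-values of the 4-group fit measure the spread between arrays of different hairpins, not between the pooled cultures. Those of the hairpin comparison measure how far differences between the arms, control included, disagreed between the 2 lines.

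Before the data were examined, the groups, fits, alternatives, 36 gene lists and a rule for naming genes were fixed. The rule took ZFX and, for each silenced against control contrast, 12 genes in each direction among those that passed and lay on the same side of control with both hairpins in each line concerned, filled up with the genes of smallest p where fewer passed. For the other contrasts it took 5 genes in each direction by p, and for any list described, its members with the smallest p first. Of the 36 lists 34 had at least 5 measured members and were tested with limma's camera, with the preset correlation of 0.01 and with an estimated correlation, adjusted over the 34 lists of a contrast. Members were also counted after adjustment over the list alone, and the list median was placed among 10000 random lists matched on mean expression in 20 bins. A size rule without a test counted genes at least 2-fold from control with both hairpins. Values expected from the shared control array were obtained from 100 simulated data sets without effects.

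The fits were tested on simulated data with 200 changed genes among 11785, in 5 data sets each, with variances drawn from the fitted prior. All simulated variances came from the 4-group fit, which counts differences between the hairpins as error. The shares given for the hairpin contrast therefore do not reflect the variances of its own fit. In the Jurkat contrast 11.4%, 69.5% and 88.4% of genes changed 2-fold, 4-fold and 8-fold were recovered, and in the K562 contrast 10.1%, 66.4% and 92.3%. In the average contrast these were 36.4%, 88.1% and 97.1%, and in the hairpin contrast 23.0%, 83.7% and 97.1%. Between 4.76% and 5.85% of calls were false. With each gene's own posterior variance in the simulation the recovery was higher, at 33.3%, 91.5% and 98.8% in the Jurkat, 33.1%, 89.5% and 99.1% in the K562, 69.6%, 98.4% and 99.4% in the average and 55.3%, 97.9% and 100% in the hairpin contrast. The share of false calls was then between 6.67% and 11.0%. For lists of 20 members shifted by 0.5 in the Jurkat contrast, camera found 20 of 20 with the preset and 18 of 20 with an estimated correlation, and 0 lists without a shift. The simulated noise was independent between genes, so this does not show how either test performs on lists whose members vary together. On the measured arrays the test with an estimated correlation passed 0 of 34 lists in every contrast, that between the lines' controls included. Failing that test therefore does not show that a list was unshifted.

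Alternatives covered quantile normalization, median centring, cyclic loess normalization, a pseudocount 4 times smaller or larger, no filter or a filter at the 75th percentile, other ways to combine probe sets, variances without an intensity trend, other fits and leaving out each silenced array in turn. Cyclic loess and a hairpin fit on the 4 silenced arrays alone were added after the data were seen. Array quality was described by the control probe sets: the hybridisation controls lay within a log2 value of 0.24 of the line's control array, the GAPDH 3'/5' ratio was between 1.15 and 1.36, and the ACTB 3'/5' ratio between 7.54 and 11.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.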

Results

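The series measured gene expression after silencing of ZFX, an X-linked zinc finger transcription factor, in human leukemia cells. Jurkat is a T cell acute lymphoblastic leukemia line, and K562 is a chronic myeloid leukemia line with erythroid features. Cells to be silenced were infected with a lentiviral short hairpin RNA and the fluorescent cells were sorted. Whether the control cells carried a control hairpin vector is not settled. If they did not, a difference to control cannot be told apart from an effect of infection and sorting. Each line had 1 control array and 2 silenced arrays, 1 for the hairpin labelled 381 and 1 for the hairpin labelled 1012, giving 6 arrays. Each array was hybridised with a pool of RNA from 3 replicates, so an array was treated as 1 sample. The spread within a silenced group is therefore the spread between 2 hairpins, and no control group had a replicate array. The 6 arrays had closely matched 2% trimmed mean signals of about 500, and arrays of the same line correlated with Pearson's r between 0.979 and 0.985 across 11785 genes. The number of arrays limits the precision of every comparison.

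ZFX signal was below that of the line's control in all 4 silenced arrays. Averaged over the 4 probe sets annotated to ZFX alone, the signal in Jurkat cells was 53.8% ± 13.6 (SD over probe sets, n = 4) of control with hairpin 381 and 39.0% ± 14.2 with hairpin 1012. In K562 cells it was 37.8% ± 14.6 with hairpin 381 and 30.7% ± 8.38 with hairpin 1012. For the brightest ZFX probe set, which represents the gene in the tests, the signal was 498 in control Jurkat cells, 337 with hairpin 381 and 119 with hairpin 1012. In K562 cells the same probe set read 719 in the control, 236 with hairpin 381 and 289 with hairpin 1012. Over both lines ZFX differed from control by a log2 value of -1.32 ± 0.36 (SE), with a limma adjusted p of 0.780 over all genes. ZFX passed when adjusted over the list alone (adjusted p = 0.0136), a list of ZFX and its paralog ZNF711, whose average log2 difference was 0.22.

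**Figure D1:**
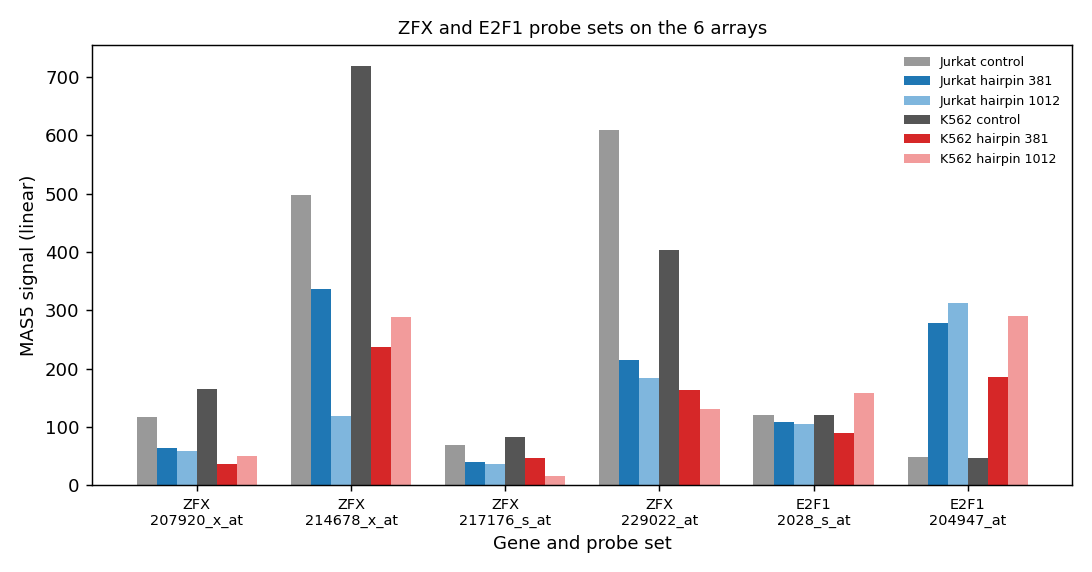
Bars give the linear MAS5 signal (y axis) on the 6 arrays, 1 bar per array and no error bars. Shown (x axis) are the 4 probe sets annotated to ZFX alone, not all of which passed the filter, and the 2 E2F1 probe sets that passed it. All ZFX probe sets read lower on the silenced arrays than on the line's control array, while 1 of the E2F1 probe sets read higher on all 4, at 185 to 312 against 49.0 and 46.0 in the controls.

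The Jurkat comparison asked which genes responded to ZFX silencing in T cell leukemia cells. The genes with the smallest p among those higher with both hairpins were CHML, a Rab escort protein, at 2.22-fold (log2 1.15 ± 0.17 SE), the cell cycle transcription factor E2F1 at 4.73-fold (log2 2.24 ± 0.38) and the alcohol dehydrogenase ADH4 at 4.70-fold (log2 2.23 ± 0.40). CHML had log2 differences of 1.14 and 1.16 with the 2 hairpins, and the other 2 CHML probe sets that passed the filter were also higher on both arrays. Both arrays were set against the same control array, so this agreement is not replication. No gene passed over all genes in Jurkat cells (limma adjusted p = 0.998 for CHML). The adducin gene ADD2, FRG1GP, PEAR1, the GTPase gene RAB20, the homeobox gene SIX4, PDLIM4 and ARHGAP5-AS1 followed, with fold values between 2.72 and 5.23. These 7 genes were dim in control Jurkat cells, with a signal of 13.7 for ADD2 and between 2.13 and 5.41 for the others, all below the pseudocount of 16.9. Their fold values depend on it: with a pseudocount 4 times larger or smaller the log2 value was 1.14 or 3.75 for RAB20, 0.59 or 2.39 for FRG1GP and 0.71 or 2.91 for PDLIM4. Of the other 4 ADD2 probe sets that passed the filter 2 were higher on both arrays, and a second PDLIM4 probe set read 0.84 and -0.060. C6orf62 and the RNA-binding protein gene LARP4 were bright genes with smaller differences of 1.63-fold and 1.65-fold, and 1 of the other 4 LARP4 probe sets was not higher on both arrays.

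Among the genes lower with both hairpins in Jurkat cells, NDRG2 had a log2 value of -1.50 ± 0.29, the adenylate kinase AK1 -1.87 ± 0.37, TLCD3A -1.51 ± 0.33, cyclin D2 (CCND2) -1.13 ± 0.26 and the Golgi mannosidase MAN1A1 -0.93 ± 0.22. VAT1, FAM78A, FBXO6, FAM30A, TNXB, PKN3 and the GTPase gene RAC3 lay between -1.58 and -1.01. AK1 was dim on the silenced arrays, with signals of 9.56 and 5.96, below the pseudocount, and lay at -0.90 or -2.70 with a pseudocount 4 times larger or smaller. TNXB lay at -1.01 with the larger one. A second NDRG2 probe set was higher, by 0.55 and 0.52, and a second MAN1A1 probe set read 0.82 and -0.10. Of the other 3 CCND2 probe sets 2 were lower with both hairpins. CCND2 was the single member of the list of cyclin-dependent kinase inhibitors and D cyclins to pass when adjusted over the list alone (adjusted p = 0.0275).

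Of 34 gene lists tested in Jurkat cells, 1 rose, that of MYC and ribosome biogenesis genes, with 16 of 20 members above control and a median log2 value of 0.13. The camera test gave adjusted p = 0.0205 with the preset correlation, and adjusted p = 0.962 with an estimated correlation. The list's highest members by p were the mitochondrial chaperonin HSPE1 (log2 0.39 ± 0.14) and the ribosome assembly gene RRS1 (log2 0.57 ± 0.24), while MYC itself had a value of -0.21. No member passed when adjusted over the list alone.

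With limma, 0 of 11785 genes passed an adjusted p of 0.05 in Jurkat cells, and 409 had an unadjusted p below 0.05. The smallest adjusted p was 0.998. The adjusted p of the list was 0.292 without the hairpin 381 array, 0.154 without an intensity trend, 0.0937 without a filter and 0.0693 after cyclic loess normalization.

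In K562 cells the comparison asked the same of a myeloid line with erythroid features. No gene passed over all genes there either, and both hairpins were again set against the same control array. Higher with both hairpins, in order of p, were the long noncoding RNA RUNX1-IT1 at 5.51-fold (log2 2.46 ± 0.40), the Src-like adaptor gene SLA at 3.08-fold (log2 1.62 ± 0.29), the myosin light chain gene MYL10 at 6.25-fold (log2 2.64 ± 0.48) and E2F1 at 3.95-fold (log2 1.98 ± 0.38). FAM111A (log2 1.11 ± 0.21), the RNA-binding protein gene CELF2 (log2 0.92 ± 0.18) and vimentin (VIM, log2 0.74 ± 0.17) were bright genes. All 7 CELF2 probe sets that passed the filter were higher on both silenced K562 arrays, while the second VIM probe set read 1.15 with hairpin 381 and -0.27 with 1012. CHN1, ALDH3A2, the hematopoietic kinase MAP4K1, BMERB1 and CFAP95 had fold values between 2.84 and 4.39. Several of these genes were dim in control K562 cells, with signals of 8.60 for RUNX1-IT1, 3.10 for SLA, 8.77 for CHN1, 11.0 for ALDH3A2 and 14.6 for BMERB1, below the pseudocount of 16.9, and 17.9 for MAP4K1 and 18.9 for MYL10. Their fold values depend on the pseudocount: the log2 value of SLA was 2.73 with a pseudocount 4 times smaller and 0.67 with one 4 times larger. Other probe sets of ALDH3A2 and MAP4K1 did not follow, a second SLA probe set read 0.070 and 0.078 at signals below the pseudocount, and the mean over the ALDH3A2 probe sets was -0.093.

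Lower with both hairpins in K562 cells were HHIP-AS1 (log2 -2.18 ± 0.30), CCDC92 (log2 -1.71 ± 0.29), DENND1C (log2 -2.04 ± 0.37), the G protein subunit gene GNG2 (log2 -1.42 ± 0.27) and ADCK2 (log2 -1.21 ± 0.25). The actin nucleator gene SPIRE1, TRO, the glycosyltransferase gene B3GNT5, the T cell kinase gene LCK, CDK2AP1, the BMP-binding protein gene TWSG1 and the desmosomal gene PKP3 lay between -1.57 and -0.84. GNG2 and LCK were dim in K562 cells, with control signals of 34.1 and 32.7, and lay at -0.54 and -0.46 with a pseudocount 4 times larger. HHIP-AS1, DENND1C and TRO were dim on the silenced arrays, with signals between 2.74 and 13.6, below the pseudocount, and DENND1C lay at -0.93 with a pseudocount 4 times larger. All 3 probe sets of ADCK2 and all 3 of SPIRE1 that passed the filter were lower on both silenced arrays, as were both of LCK and both of TWSG1. Others did not follow: with hairpins 381 and 1012 a second GNG2 probe set read -1.15 and 0.37, a second B3GNT5 probe set 0.13 and 0.69, and the other TRO probe sets -0.52 and 0.051, and 0.26 and -1.37.

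The list of ATF4 and unfolded protein response genes rose in K562 cells, with 18 of 21 members above control and a median log2 value of 0.37. Its members with the smallest p were the stress transcription factors ATF3 (log2 1.22 ± 0.40) and ATF4 (log2 0.51 ± 0.17), and none passed when adjusted over the list alone. The camera test gave adjusted p = 0.00313 with the preset correlation, and adjusted p = 0.947 with an estimated correlation. The list's median was 0.68 above control with hairpin 1012 and 0.09 with hairpin 381. Without the hairpin 1012 array the adjusted p was 0.673. The poly-A spike-in probe sets were also highest on the hairpin 1012 array, with a median log2 value of 0.72 above control, against 0.35 with hairpin 381.

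With limma, 0 of 11785 genes passed in K562 cells. An unadjusted p below 0.05 was reached by 579, and the smallest adjusted p was 0.898, for HHIP-AS1 and others.

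Averaged over both lines, E2F1 had the smallest p of all genes, with 4.32-fold more signal in silenced cells (log2 2.11 ± 0.27 SE, limma adjusted p = 0.570). Its log2 differences to control were 2.16 and 2.32 in Jurkat cells and 1.68 and 2.28 in K562 cells, for hairpins 381 and 1012. The control signals of that probe set, 49.0 and 46.0, lay near the lower end of the values kept. The second E2F1 probe set differed by -0.14, -0.17, -0.37 and 0.35 on the same arrays. E2F1 was also the single member of the G1/S replication list to pass when adjusted over the list alone (adjusted p = 0.0014), while the list as a whole had 13 members above and 16 below control, a median of -0.012 and a mean of 0.017.

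Next by p among the genes higher on all 4 silenced arrays were SERINC1 (log2 0.72 ± 0.15), the N-glycan glucosyltransferase ALG5 (log2 0.85 ± 0.18), the Rab GTPase genes RAB13 (log2 0.83 ± 0.19) and RAB27B (log2 1.27 ± 0.31), the membrane insertion gene GET1 (log2 0.56 ± 0.13) and TVP23B (log2 0.79 ± 0.19). BTF3P12, the gamma-tubulin complex gene MZT1, FRG1GP, the chaperonin-like gene BBS10 and MRFAP1L1 were higher by log2 values between 0.55 and 1.34. Both ALG5 probe sets that passed the filter were higher on all 4 arrays. The second probe sets of MZT1 and RAB27B were not higher on all of them. RAB13 and FRG1GP were dim in control Jurkat cells, with signals of 3.24 and 4.36, and their averages were 0.47 and 0.52 with a pseudocount 4 times larger.

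Lower on all 4 silenced arrays were CCDC92 (log2 -1.18 ± 0.21), HHIP-AS1 (log2 -1.20 ± 0.21), B3GNT5 (log2 -1.25 ± 0.23), TLCD3A (log2 -1.21 ± 0.23), SPIRE1 (log2 -1.02 ± 0.20) and VAT1 (log2 -0.91 ± 0.18). FBXO6, the syntrophin gene SNTB2, DESI2, KLHL42, NDRG2 and DENND1C lay between -1.42 and -0.82. HHIP-AS1 lay at -0.021 and -0.42 in Jurkat and at -2.31 and -2.04 in K562 cells, and DENND1C at -0.17 and -0.41 in Jurkat and at -1.96 and -2.12 in K562 cells, so their averages came mostly from dim K562 signals. A second B3GNT5 probe set that passed the filter had positive values on all 4 arrays, and of the 4 DESI2 probe sets that passed it 2 were lower on all 4 arrays. Of the other 3 SNTB2 probe sets that passed it 1 was lower on all 4.

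The list of beta-galactosyltransferases, which add galactose to glycans, fell on average over the lines. Of 8 members 7 were below control, with a median log2 value of -0.31 and a camera adjusted p of 0.0284 with the preset correlation. The adjusted p was 0.949 with an estimated correlation. B4GALT1 was below control on all 4 arrays, by -0.82, -0.40, -0.99 and -0.90 (average -0.78 ± 0.21 SE), and passed when adjusted over the list alone (adjusted p = 0.0461) but not over all genes (limma adjusted p = 0.780). B4GALT5 followed with an average of -0.69 ± 0.27. This list was drawn up with published work on ZFX in leukemia cells in mind, which may include these samples, so its direction is not independent evidence. The list's adjusted p was 0.130 without the Jurkat hairpin 1012 array, 0.217 with the mean of probe sets per gene, 0.147 with every probe set on its own and 0.0549 without an intensity trend.

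**Figure D2:**
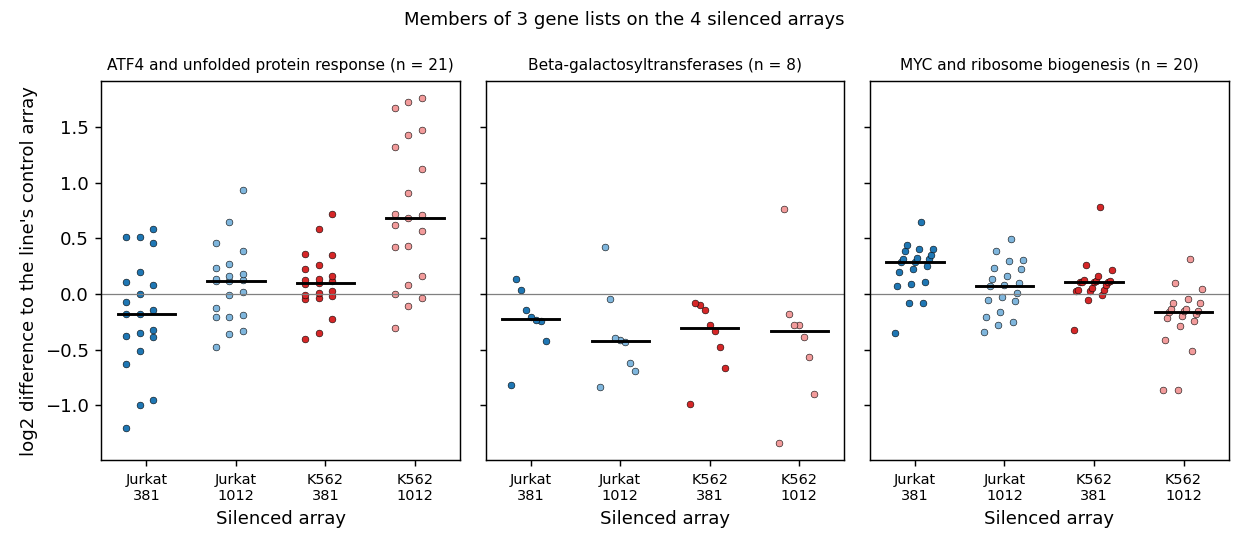
Each point is the log2 difference of a list member to the control array of its line (y axis) on each of the 4 silenced arrays (x axis), in 3 gene lists with 21, 8 and 20 members, and black lines are medians. The median of the ATF4 and unfolded protein response list was 0.68 on the K562 hairpin 1012 array and between -0.18 and 0.12 on the others, and the beta-galactosyltransferase medians lay between -0.42 and -0.22.

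Averaged over both lines, 0 genes passed with limma, and 713 had an unadjusted p below 0.05. Without the K562 hairpin 381 array 2 genes passed, E2F1 and MZT1, with a smallest adjusted p of 0.0188.

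By size alone, 58 genes were at least 2-fold higher and 27 at least 2-fold lower with both hairpins in Jurkat cells, and 65 and 67 in K562 cells. Simulated data without effects, in which both hairpins share a control array, gave means between 26.1 and 27.3 genes and at most 47. The simulated noise was independent between genes, so its range can be too narrow and does not show that the observed counts exceed noise. By this rule E2F1 was the single gene higher, and B3GNT5 the single gene lower, with both hairpins in both lines, and PDLIM4, named after its values were seen, was higher in Jurkat and lower in K562 cells. The simulated data gave means of 0.45 higher, 0.44 lower and 0.90 opposite genes and at most 3, 3 and 4, so each of these counts lay within the simulated range. Independent lists of these sizes would share 0.32 and 0.15 genes. B3GNT5 was dim on all 3 Jurkat arrays, with signals below 54.4 in the control and of 3.51 and 3.46 with the hairpins, so its Jurkat value depends on the pseudocount. It was bright in K562 cells, at 3486 in the control and 1428 and 1108 with the hairpins. The size rule depended on the pseudocount: 4 times smaller, it gave 176 genes in Jurkat and 241 in K562 cells, and 4 times larger, 10 and 21.

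Across genes, which are not independent replicates, the mean silencing effects of the lines correlated with Pearson's r = 0.207 and Spearman's rho = 0.245, and 59.3% of genes had the same sign. This r was 0.0881 without a filter and 0.358 with a filter at the 75th percentile. Simulated data without effects gave r = -0.000821 and at most 0.0264. Noise in these simulations was independent between genes and arrays, which alone keeps r small. The simulated range therefore does not show that the observed r exceeds noise. The same hairpin correlated across the lines with r = 0.204 for 381 and 0.215 for 1012, and different hairpins with 0.0987 and 0.0891. Within a line the hairpins correlated with r = 0.470 in Jurkat and 0.468 in K562 cells, where sharing the control array alone gave a higher mean than observed in each line, and at most 0.529 and 0.526. Their covariance was 0.0781 in Jurkat and 0.0977 in K562 cells, against 0.0767 simulated for each. The simulated control arrays varied as much as the silenced arrays, with a spread taken from the differences between the hairpins. These values therefore cannot show whether the hairpins shared an effect beyond the control array.

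The difference between the lines in the silencing effect was tested as an interaction. Among the genes with a higher effect in K562 cells the smallest p values were those of MYL10 and RUNX1-IT1, above control on both silenced K562 arrays and below it on both silenced Jurkat arrays, with interaction log2 values of 3.56 ± 0.68 and 2.85 ± 0.56. ACSM3, an acyl-CoA synthetase, had log2 values of 1.08 and 1.08 in K562 and -1.06 and -0.79 in Jurkat cells, and ALDH3A2 and MAP4K1 had interaction values of 1.77 and 1.91. In the other direction were PDLIM4, which had the smallest p of all genes (-2.85 ± 0.54), CHML (-1.18 ± 0.24), GNG2 (-1.91 ± 0.39), HHIP-AS1 (-1.95 ± 0.43) and ADH4 (-2.41 ± 0.57). None of these genes passed (limma adjusted p = 1.00 for each). A second ACSM3 probe set had positive values in both lines. Several of these values rest on dim signals and depend on the pseudocount: 4 times larger or smaller, it gave 2.36 or 4.19 for MYL10 and -1.74 or -4.08 for PDLIM4.

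As groups, 3 lists differed between the lines by camera with the preset correlation. The ATF4 and unfolded protein response list was higher in K562 (median interaction 0.43, adjusted p = 0.0159), the MYC and ribosome biogenesis list lower (median -0.21, adjusted p = 0.0159) and the histone list lower (median -0.49, adjusted p = 0.0222). With an estimated correlation the adjusted p was 0.979 for each. The histone genes with the smallest p were H2AC6 (interaction -0.85 ± 0.37) and H2BC6 (-1.19 ± 0.57), and neither passed. Histone medians against control with 381 and 1012 were 0.47 and 0.26 in Jurkat cells, and 0.034 and -0.24 in K562 cells. All measured histone genes read lower in the Jurkat than in the K562 control. With limma 0 genes passed the interaction test, and 289 had an unadjusted p below 0.05. Without the K562 hairpin 1012 array the adjusted p of the lists became 0.799, 0.772 and 0.0746, and without the Jurkat hairpin 381 array 0.0874, 0.229 and 0.0874. Without a filter it was 0.0529 for each, and with a pseudocount 4 times larger it was 0.0551 for the histone list.

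The hairpins themselves were compared with the cell line as a block, to see which differences belonged to a hairpin rather than to both. With limma 109 genes differed at an adjusted p of 0.05, of which 42 were higher and 67 lower with hairpin 381 than with 1012. SMC1A, a core subunit of cohesin, had the smallest p: it was 3.45-fold lower with hairpin 381 (log2 -1.79 ± 0.11, limma adjusted p = 0.000421). Against control it was at -1.82 in Jurkat and -1.67 in K562 cells with hairpin 381, and at 0.06 and 0.02 with 1012. The phospholipase subunit gene PAFAH1B2 (log2 -1.37 ± 0.12), the endoplasmic reticulum protein gene ERP29 (log2 -1.47 ± 0.13) and FAM8A1 (log2 -1.50 ± 0.15) showed the same order, with hairpin 381 below control in both lines. Of the other 2 SMC1A probe sets 1 was lower with 381 than with 1012 in both lines and 1 in K562 cells alone, and the second PAFAH1B2 probe set was lower in K562 cells alone.

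Hairpin 1012 had the lower values for TAF13, a subunit of the general transcription factor TFIID (log2 1.71 ± 0.15 for 381 minus 1012), the selenoprotein gene SELENOT (1.41 ± 0.14), the nuclear pore gene NUP43 (1.04 ± 0.11), the methionine adenosyltransferase subunit gene MAT2B (1.25 ± 0.13) and the endocytosis gene EPS15 (1.28 ± 0.14). All 5 were below control with 1012 in both lines. The neuronal splicing regulator PTBP2 differed by -1.79 ± 0.17 because it was 1.33 and 1.86 above control with hairpin 1012. These 10 genes had limma adjusted p values up to 0.00407. Of the 109 genes, 52 were farther from control with hairpin 381 and below it, 37 farther with 1012 and below it, 5 farther with 381 and above it, and 15 farther with 1012 and above it.

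**Figure D3:**
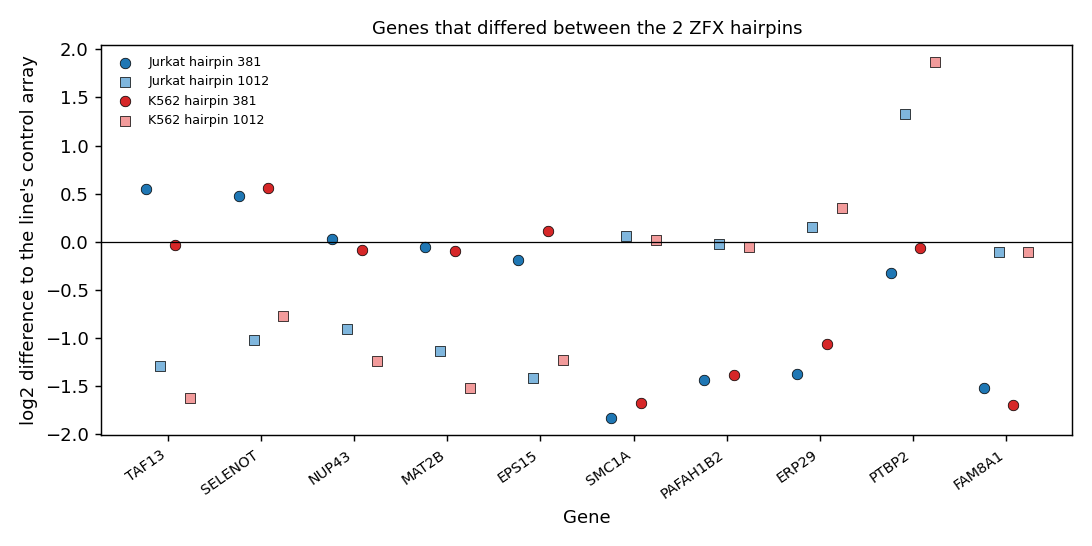
Points give the log2 difference to the control array of the line (y axis) for the 10 genes named by the hairpin comparison (x axis), circles for hairpin 381, squares for hairpin 1012, blue for Jurkat and red for K562, with no error bars. SMC1A lay at -1.82 and -1.67 with hairpin 381 and at 0.06 and 0.02 with hairpin 1012, and PTBP2 lay 1.33 and 1.86 above control with hairpin 1012.

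Gene groups differed between the hairpins too, 10 of 34 lists by camera with the preset correlation. With an estimated correlation none of the 10 passed (adjusted p = 0.749 for each). Lower with hairpin 381 than with 1012 were the ATF4 and unfolded protein response list (median -0.56, adjusted p = 0.000301), the G2/M and mitosis list (median -0.10, adjusted p = 0.000958) and the tRNA synthetase list (median -0.16, adjusted p = 0.0248). In the first, 9 members were lower and 1 was higher when adjusted over the list alone, and the serine synthesis enzyme PHGDH (log2 -1.42 ± 0.25, limma adjusted p = 0.0411) also passed over all genes. In the G2/M list the spindle genes NUSAP1 (log2 -0.92 ± 0.10, adjusted p = 0.00407) and KIF11 (log2 -0.82 ± 0.15, adjusted p = 0.0485) passed over all genes. The G2/M median against control was 0.12 with both hairpins in Jurkat cells. In K562 cells it was -0.08 with 381 and 0.12 with 1012.

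Higher with hairpin 381 were the MYC and ribosome biogenesis list (median 0.21, adjusted p = 0.00082), oxidative phosphorylation (median 0.12, 20 of 20 members, adjusted p = 0.00112), cholesterol synthesis (median 0.21, adjusted p = 0.00711), type I interferon response (median 0.40, adjusted p = 0.0103), heat shock (median 0.16, adjusted p = 0.0103), cytosolic ribosomal proteins (median 0.08, adjusted p = 0.0103) and Notch genes (median 0.32, adjusted p = 0.0417), all 7 calls being lost with an estimated correlation (adjusted p = 0.749 for each). NDUFS1, a subunit of respiratory complex I (log2 0.98 ± 0.13, limma adjusted p = 0.0099), and the sterol enzyme SQLE (log2 0.61 ± 0.10, adjusted p = 0.0289) passed over all genes. Interferon medians against control with 381 and 1012 were 0.14 and -0.12 in Jurkat cells, but 0.16 and 0.24, the other order, in K562 cells. Cholesterol medians were 0.22 and -0.22 in Jurkat cells and -0.17 and -0.20 in K562 cells. The medians of the other lists kept the same order in both lines. The ribosomal protein list turned direction after quantile normalization (adjusted p = 0.950). With cyclic loess its camera adjusted p was 0.778. Heat shock reached 0.0520 with quantile normalization and 0.0639 with cyclic loess. Notch genes reached 0.0541 with a pseudocount 4 times smaller. With a filter at the 75th percentile the camera adjusted p was 0.0635 for Notch genes and 0.0506 for tRNA synthetases.

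The hairpins also differed in 2 array controls: the poly-A spike-in probe sets were higher with 1012 than with 381 by a median log2 value of 0.36 in Jurkat and 0.38 in K562 cells, and the 3'/5' signal ratio of ACTB was 8.43 against 9.99 in Jurkat and 7.54 against 8.61 in K562 cells. On the control arrays that ratio was 9.27 in Jurkat cells, between the hairpins, and 11.1 in K562 cells, above both. The K562 spike-ins were above control with 381 too (median 0.35), so silenced and control K562 arrays differed in these controls as well. The count of genes was 63 without the K562 hairpin 1012 array and 235 without the Jurkat hairpin 1012 array, and 0 genes passed when the variance was modelled without an intensity trend. The count was 16 with the mean of probe sets per gene and 192 with a filter at the 75th percentile.

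The list calls rested on single arrays. Without the K562 hairpin 1012 array 8 of the 10 lists no longer passed, with adjusted p between 0.143 and 0.318, among them the ATF4 and unfolded protein response list at 0.166 and the MYC and ribosome biogenesis list at 0.299. The cholesterol and interferon lists still passed there. Without the K562 hairpin 381 array the adjusted p was 0.326 for G2/M, 0.165 for oxidative phosphorylation and 0.193 for both the ribosomal protein and the Notch list. Without the Jurkat hairpin 381 array it was 0.168 for tRNA synthetases and 0.232 for cholesterol synthesis, and without the Jurkat hairpin 1012 array 0.0784 for cholesterol synthesis and 0.0884 for the interferon list. Without an intensity trend 4 lists passed.

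The control arrays of the lines were compared as a check of the labels. K562 cells expressed the erythroid genes RHAG (log2 9.08 ± 0.31 higher), HBE1 (9.26 ± 0.32) and HBZ (10.12 ± 0.37), the cancer-testis gene MAGEA6 (8.92 ± 0.30) and the epithelial gene EPCAM (8.54 ± 0.32) far above Jurkat cells. Jurkat cells expressed the T lineage genes SATB1 (log2 -9.18 ± 0.32 for K562 minus Jurkat), ETS1 (-8.48 ± 0.30) and LCK (-8.27 ± 0.31), the chemokine receptor CXCR4 (-8.95 ± 0.31) and the DNA sensor IFI16 (-7.27 ± 0.29) far above K562 cells. These 10 genes had limma adjusted p values up to 6.94e-06. In the line with the lower level all but IFI16, at 67.8, had control signals below 54.4, so the sizes depend on the pseudocount: HBZ lay between 8.38 and 11.38 and SATB1 between -10.24 and -7.57 with a pseudocount 4 times larger or smaller. Of 25 T cell genes 23 were lower in K562 cells over all genes and 24 when adjusted over the list alone, and of 17 erythroid genes 14 were higher over all genes, and 15 higher and 1 lower over the list alone. All 10 histone genes were higher in K562 cells, with a median log2 value of 5.31.

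In all, 1822 genes were higher and 2245 lower in K562 than in Jurkat controls. The comparison has 1 array per line, and its error was taken from the spread between hairpins. By camera with the preset correlation the T cell (adjusted p = 6.14e-16), histone (adjusted p = 3.99e-09), erythroid (adjusted p = 7.90e-08), fibroblast and epithelial (adjusted p = 0.000211), tRNA synthetase (adjusted p = 0.00496) and type I interferon (adjusted p = 0.0300) lists differed, the first and the last being lower in K562. With an estimated correlation none passed, the smallest adjusted p being 0.445.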

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

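The tests of explanations in this part were chosen after the results were seen.

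The silencing effect differed between the cell lines in 3 gene lists by the interaction test with the preset correlation. The median difference, K562 minus Jurkat, was -0.21 for MYC and ribosome biogenesis genes, 0.43 for ATF4 and unfolded protein response genes and -0.49 for histone genes. With an estimated correlation none of the 3 passed (adjusted p = 0.979 for each).

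Probe sets outside the gene comparisons also read above control. All 24 poly-A spike-in probe sets were above the line's control with hairpin 1012, with medians of 0.45 in Jurkat and 0.72 in K562 cells on the log2 scale. The 5' control probe set for 28S ribosomal RNA was above control by 0.87 and 0.83 on the silenced Jurkat arrays with hairpins 381 and 1012.

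The higher ATF4 and unfolded protein response genes in K562 cells were weighed against 3 explanations, and all 3 stay open. A low reading of the single K562 control array would raise both silenced arrays alike, and the median member differed between them by 0.62, against a mean shift of 0.42. Under an equal response to ZFX loss by both hairpins the list would be high with 381 as well, and its median there was at percentile 93.2 of matched random lists. Under an effect of hairpin 1012 in both lines the members would be higher with 1012 in Jurkat cells too, and the median difference to 381 was 0.26. Against the Jurkat control the list's median was 0.12 with 1012 and -0.18 with 381, so much of that gap came from low values with 381. These values compare single arrays over genes that vary together, so the explanations were not told apart. The rule for deciding also required the list to pass camera between the hairpins with an estimated correlation (adjusted p = 0.749). No list passed that test in any contrast, so the rule left all 3 open whatever the other values were.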

How the results depend on the processing

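The count of genes that passed in any comparison of silenced with control cells was 0 under all settings with every array in, and the ZFX level kept its direction under all of them. Cyclic loess and the fit on the 4 silenced arrays alone were chosen after seeing the data. The hairpin of each silenced array was also used as a replicate block, since the labels' replicate numbers follow the hairpins. That block left the counts at 0 with limma, with 804, 1039 and 1322 genes at an unadjusted p below 0.05 in Jurkat, in K562 and on average, against 409, 579 and 713 without it, and a smallest adjusted p of 0.0760 on average. It left the average ZFX level at -1.32, and gave 3 shifted lists in Jurkat and 2 on average. Unless stated, the cause of a change was not tested. Signal over background limits the results: settings that admit dim probe sets or weight them more, no filter and a smaller pseudocount, gave more genes by the size rule.

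With a pseudocount 4 times smaller the size rule gave 176 genes in Jurkat, 241 in K562 and 4 in both lines, and with a pseudocount 4 times larger 10, 21 and 1, with 3 lists in Jurkat. Without a filter it gave 438, 592 and 13 genes, with 0 lists in Jurkat, 2 in K562 and 0 for the interaction, and the lines correlated with r = 0.0881. With a filter at the 75th percentile, which tests fewer genes, it gave 8, 24 and 0 genes, with 4 lists in Jurkat and 4 in K562, 192 hairpin genes, 2314 genes between the lines and r = 0.358. With the mean of probe sets per gene there were 3 lists in Jurkat, 0 on average, 16 hairpin genes and 0 genes 2-fold in both lines, and ALDH3A2 in K562 turned to -0.093. With every probe set on its own there were 4 lists in Jurkat, 2 in K562, 2 on average and 7 for the interaction, 210 hairpin probe sets, 7700 between the lines, and 208, 289 and 8 by the size rule. Without an intensity trend there were 0 lists in Jurkat, 0 on average, 0 for the interaction and 4 between hairpins, and 0 hairpin genes. Median centring gave 5 interaction lists. Cyclic loess gave 6 interaction lists and 1 gene 2-fold in both lines, E2F1. The fit on the silenced arrays alone gave 59 hairpin genes, 58 of them among the 109. After quantile normalization the ribosomal protein list turned to lower with hairpin 381 (adjusted p = 0.950).

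Leaving out each silenced array in turn, a fit in which a lone array is assumed to vary like the other groups, gave 0 genes in Jurkat, in K562 and for the interaction, 0 to 2 on average, 63 to 235 between hairpins and 3979 to 4521 between the lines. The lists that passed numbered 0 to 1 in Jurkat, 0 to 5 in K562, 0 to 4 on average, 1 to 7 for the interaction, 2 to 11 between hairpins and 6 to 6 between the lines. The ZFX level was -1.92 to -0.54 in Jurkat, -1.54 to -1.27 in K562 and -1.66 to -0.97 on average, and the lines correlated with r = 0.172 to 0.183. The lowest list counts in K562, and between hairpins, came without the K562 hairpin 1012 array.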

Other observations

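The tests of explanations in this part were all chosen after the results were seen. In K562 cells lineage genes lay on both sides of control, and none passed the test. The embryonic globin HBZ was below control with both hairpins, at -1.12 and -1.38 (log2 -1.25 ± 0.32 SE), while the adult globins HBB (1.06 ± 0.41) and HBD (0.99 ± 0.40) were above it, all with limma adjusted p of 0.898 or more. The erythroid list had 3 members above and 14 below control in K562 cells, with a median of -0.18 and a camera adjusted p of 0.343. Among T cell genes, which are dim in K562 cells, the receptor chain CD247 lay above control (1.23 ± 0.31) and LCK (-1.16 ± 0.27) and CD28 (-1.01 ± 0.29) below it.

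No list of cell death or cycle arrest genes passed on average over the lines. Of 19 pro-apoptotic genes 8 were above and 11 below control on average over the lines, with a median of -0.032, a test pointing up and a camera adjusted p of 0.896, and of 8 anti-apoptotic genes 3 were above and 5 below, also with 0.896. BIK, a pro-apoptotic BH3-only gene, was above control on all 4 silenced arrays (0.30, 0.42, 1.18 and 1.29; average 0.80 ± 0.21), and BAD, of the same class, was below it on all 4 (-0.53, -0.68, -0.88 and -1.32; average -0.85 ± 0.24). The kinase inhibitor CDKN2D was above control on all 4 (average 0.87 ± 0.24). These 3 genes had limma adjusted p = 0.780. Of 12 cyclin-dependent kinase inhibitors and D cyclins 9 were above control on average (median 0.10, camera adjusted p = 0.543) and 9 in K562 cells (median 0.19, adjusted p = 0.244). In Jurkat cells 7 were above it, with a median of 0.095, a mean of -0.038 and a test pointing down (adjusted p = 0.993). The p53 target list, with 7 members above and 10 below control, had a camera adjusted p of 0.928.

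E2F1 read higher on all 4 silenced arrays through a single probe set. A rise of the whole transcript was argued against by the second E2F1 probe set, with a mean log2 difference of -0.082 ± 0.30 (SD, n = 4). This holds only if that probe set responds to the level of E2F1, which was not tested. More cells in the G1/S phase would raise the other G1/S replication genes, and the median of those 28 genes, averaged over the 4 silenced arrays, was -0.050 ± 0.057 (SD over arrays). A sequence carried by the silenced cells and read by that probe set would add a like signal to every silenced array, and the highest added signal was 1.90 times the lowest. A longer or shorter E2F1 transcript predicts the same, so these may not be told apart here.

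The hairpins differed in 109 genes with the line as a block. A deeper ZFX knockdown by 1 hairpin as the whole cause would place nearly all of them farther from control with that hairpin, and was argued against: 52.3% (95% Wilson interval 43.0% to 61.4%, which treats genes as independent) were farther with hairpin 381 and the others with 1012. Lowering of other transcripts by each hairpin, a known property of short hairpin RNAs, is a candidate explanation: 81.7% of the 109 genes (interval 73.4% to 87.8%) were below control with the hairpin farther from it, against 52.2% of all genes. Joint processing of each hairpin's RNA in both lines cannot be told apart from the hairpin, since the poly-A spike-in probe sets were higher with 1012 by a median of 0.38 in K562 and 0.36 in Jurkat cells.

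Probe sets without a single gene symbol were examined as well. Of 4996 that passed the filter, 0 passed in any comparison of silenced with control cells with limma, and 32 differed between the hairpins. The single one at least 2-fold from control on all 4 silenced arrays, chosen after its values were seen, was lower, with log2 values of -1.75, -1.33, -1.05 and -1.02. It was dim in K562 cells, with a signal of 20.7 in the control and of 1.30 and 1.63 with the hairpins, so its K562 values depend on the pseudocount of 16.9.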
